A study of Homo sapiens with 6 samples.

How the data were processed

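RNA was extracted from 6 xenograft tumours of the 1205Lu melanoma line, labelled with biotin by the Affymetrix protocol and measured on arrays, per the labels' protocols. The groups are the non-target control (3 samples) and the SHP2 knockdown (3 samples), each sample taken from its own label. The array design, the genome build and the version of the software are not given in the sources used here; the descriptions of some features quote GRCh37 positions. The authors processed the scans with GCRMA, per the submitters' processing notes. As commonly defined, GCRMA subtracts background by probe sequence, normalizes between arrays and summarises the probes of a feature. The deposited values range from 0.05 to 13.3 and are read here as log2 values, since the base is not stated. The deposited table with gene annotation and the series value table are the same in each cell (largest difference 0), so the second is no independent check. The scanner files were not used here, nor were detection flags, so a feature's level was set against 3575 features that the table marks as negative controls, whose 95th percentile was 5.90, 5.43 and 5.12 in control tumours 1 to 3 and 5.43, 5.18 and 5.09 in knockdown tumours 1 to 3.

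The table holds 53617 features. Of these, 26419 carry 1 gene symbol (24494 distinct symbols), 270 several and 26928 none. Features with several symbols or none, and control features, stayed out of the gene comparison. The feature with the highest mean over the 6 arrays stood for each gene, and genes were kept where at least 3 of the 6 arrays were above a log2 value of 4, which left 12541. This filter is permissive: 7006 genes exceed the 95th percentile of negative controls in at least 3 arrays. No kept feature of a named gene differed in direction from the one that stood for it. Gene names are those of the deposited table and can be old, and 12155 of the kept symbols are current symbols or synonyms in the reference gene table.

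Groups were compared with limma 3.58.1 (lmFit and eBayes, no trend, no covariate, all 6 arrays) in R 4.3.3, with two-sided tests and Benjamini-Hochberg adjustment over the genes kept, at a threshold of 0.05. The fit had 4 residual degrees of freedom and 5.83 prior degrees of freedom. Intervals are 95% intervals of the moderated fit. For PTPN11 an exact two-sided permutation test over the 20 assignments was added. Before the data were examined, 37 gene lists were fixed, including markers of other cell types and, for RNA quality, heat shock and immediate early genes. The 31 lists with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01, with an estimated correlation, and with fry. Of the 792 genes listed, 783 matched a gene of the table.

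The rule for the genes named was fixed beforehand too. It takes PTPN11 first, then per direction the 10 genes with the largest change among those past the threshold whose groups do not overlap, filled up with the non-overlapping genes of smallest p. From each list described it takes 2 to 4 members, those past the threshold and then those of smallest p; for lists of other cell types and RNA quality it takes the members with the highest mean level. Only PTPN11 passed, so all other places were filled by p. Of the list members that the rule names, 1 is not reported here.

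The tests were checked on simulated data for this comparison, with 12541 genes, independent noise and 200 changed genes, 50 per size. The genes had the real means and the moderated variances of the fit. Those are drawn toward a common value, so the most variable genes were simulated with less spread than observed. limma called 10.0% of changes of 0.5 log2 units, 84.0% of changes of 1 and 100.0% of changes of 1.5 and of 2, with the right direction in 100.0% of calls, and 12 unchanged genes. A simulated shift of 0.3 in the interferon list gave a camera adjusted p of 2.14e-13, with 0 of the other lists called. The simulation holds no differences shared between genes of an array, which the real arrays have. Its 200 changed genes also make the adjustment less strict than it is where few genes change.

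The alternatives fixed beforehand were 2 other low-value filters, 2 other ways to stand for a gene, the series value table, 2 further normalizations, 3 other variance models, the sample number as a block, a threshold of 0.1, every feature tested singly, other list tests and leaving out each array. Added after the data were seen were a covariate for the contrast of positive and negative control features, a fit without both arrays numbered 1, and a filter at the negative control percentile. Pairwise correlations between arrays over all features ran from 0.960 to 0.983, and no 2 arrays held the same data.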

Results

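Gene expression was measured on arrays in subcutaneous xenograft tumours of 1205Lu, a human cell line derived from a metastatic melanoma, grown for about 6 weeks in NSG mice, a strain that lacks mature lymphocytes and natural killer cells. The tumour cells carried either a non-target short hairpin RNA (control, 3 tumours) or a short hairpin RNA against SHP2 (knockdown, 3 tumours). SHP2, the product of PTPN11, is a protein tyrosine phosphatase that transmits signals from receptor tyrosine kinases to the RAS-ERK pathway. The comparison asks which transcripts differ between knockdown and control tumours. The labels number the samples of each group from 1 to 3 but do not say whether each tumour came from a separate mouse, so p-values measure only the spread between these samples. After 1 feature per gene was chosen and low values were removed, 12541 genes were compared. Values are log2 GCRMA values, and differences are knockdown minus control. The precision is limited by the number of arrays (3 per group), and the median standard error of a difference was 0.19 on the log2 scale.

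PTPN11 fell in the knockdown tumours. Its value was 8.76 ± 0.29 (SD, n = 3) in control tumours and 6.71 ± 0.32 (SD, n = 3) in knockdown tumours, a fall to 24.2% of the control level on the linear scale (95% interval 17.3 to 33.7%). The 3 knockdown values, 6.92, 6.34 and 6.88, all lay below the 3 control values, 8.47, 8.76 and 9.05, and all 6 lay above the 95th percentile of the negative control features of the same array. PTPN11 is represented by a single feature, 16757255. The log2 difference of -2.05 (SE 0.21) had an unadjusted limma p of 2.73e-06 and a Benjamini-Hochberg adjusted p of 0.034 over the 12541 genes. In the exact two-sided permutation test, p was 0.1, the smallest that 3 samples against 3 can give. The log2 difference lay between -2.19 and -1.86 when any 1 array was left out. The adjusted p was then 0.021 without control 1 but 0.27, 0.096, 0.15, 0.20 and 0.15 without control 2, control 3, knockdown 1, knockdown 2 and knockdown 3.

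**Figure D1:**
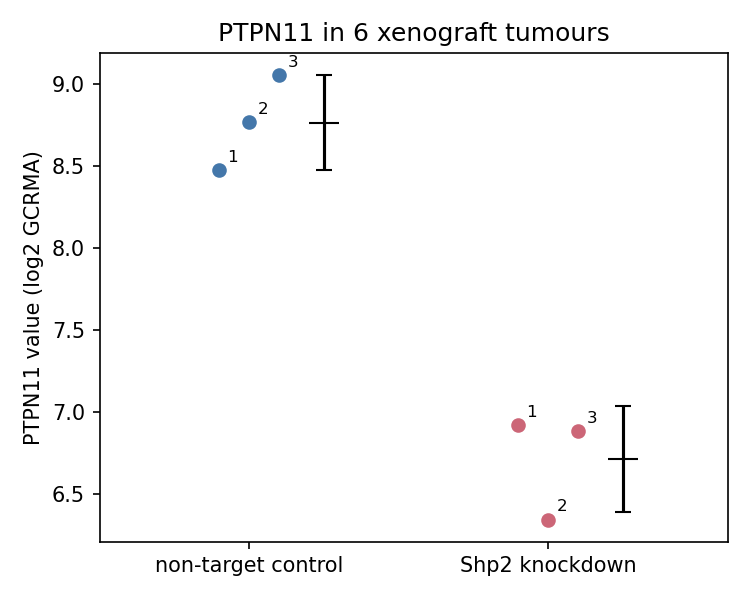
PTPN11 values (log2 GCRMA, vertical axis) in the non-target control and SHP2 knockdown tumours, with 1 point per tumour labelled by its sample number and black bars for the group mean ± SD (n = 3). The control tumours lie between 8.47 and 9.05 and the knockdown tumours between 6.34 and 6.92.

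PTPN11 was the only gene that passed the adjusted threshold of 0.05. No gene rose past it, and PTPN11 was also the only gene past the threshold with a change of at least 2-fold. At an unadjusted p under 0.05 there were 319 genes, 2.54% of those compared, below the 5% that chance alone gives. The groups did not overlap for 836 genes (6.67%), against the 10% that chance gives for 3 samples against 3. Under the other tools, an ordinary per-gene test without variance moderation called 0 genes, and limma with array quality weights called 1 gene, PTPN11. Without control 2, control 3, knockdown 1, knockdown 2 or knockdown 3 the count was 0, and without both arrays numbered 1 it was 2 genes, PTPN11 and the small nucleolar RNA gene SNORD113-3, with the latter named after its value was seen.

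The genes with the smallest p and no overlap between the groups are given as values, since none of them except PTPN11 passed the test (adjusted p of 1.00 for each in limma). Among the 10 with higher values in knockdown tumours, NRP1, a receptor for semaphorins and VEGF, was 8.43 ± 0.18 in control and 9.10 ± 0.21 in knockdown tumours (difference 0.68, SE 0.17). SEMA7A, a membrane-anchored semaphorin, was 6.91 ± 0.06 against 7.87 ± 0.58. STC1, which encodes the secreted glycoprotein stanniocalcin 1, was 6.87 ± 0.17 against 7.64 ± 0.27. PHLPP2, a phosphatase that acts on AKT, was 4.05 ± 0.11 against 4.73 ± 0.23, below the 95th percentile of negative controls in all 6 arrays. The non-coding genes SNAR-H, SNAR-D and SNAR-E had differences of 1.06, 0.87 and 0.85. SNAR genes are near-identical copies whose features can read the same transcripts, so they are uncertain as separate genes. The other members were LOC100131262 (0.90), ACPP, which encodes prostatic acid phosphatase (0.60), and SMAGP, which encodes a small transmembrane glycoprotein (0.59).

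Among the 10 with lower values in knockdown tumours, after PTPN11, MAP3K5, the stress-activated kinase ASK1, was 7.39 ± 0.21 in control and 6.66 ± 0.09 in knockdown tumours, 1.65 times higher in control. GAS5, a non-coding host gene of small nucleolar RNAs, was 6.51 ± 0.09 against 5.91 ± 0.10. SCARNA9, a small Cajal body RNA, was 8.64 ± 0.04 against 8.07 ± 0.18. F13A1, the A subunit of coagulation factor XIII, was 5.31 ± 0.34 against 4.47 ± 0.12 and exceeded the 95th percentile of negative controls in 1 array. MIR21 (-0.95), RN5S474 (-1.13), RAB44 (-0.66) and ANKRD18A (-0.61) exceeded that percentile in 0 of the 6 arrays, and MIR644A (-1.29) in 2. RN5S474 is a copy of the 5S ribosomal RNA gene, whose copies are similar in sequence.

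**Figure D2:**
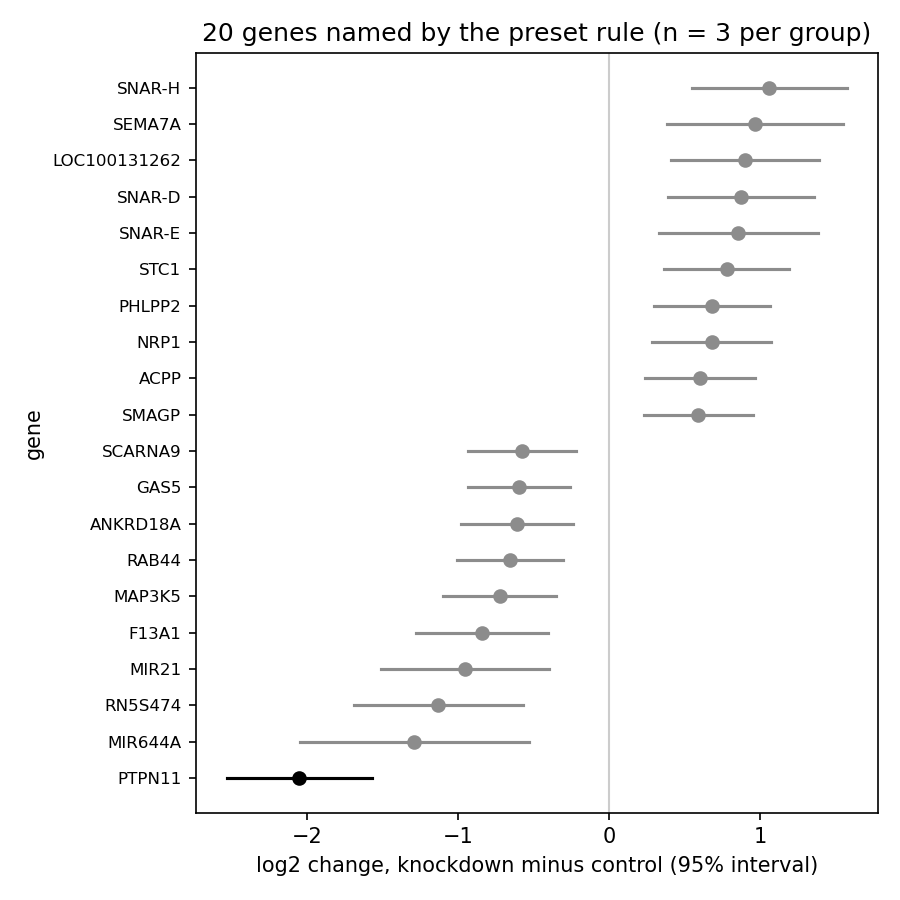
Log2 difference, knockdown minus control, of the 20 genes named by the preset rule (horizontal axis), with 1 row per gene and lines for the 95% interval from limma (n = 3 per group). PTPN11, in black at -2.05, is the only gene past the adjusted threshold, and the other 19, in grey, range from -1.29 (MIR644A) to 1.06 (SNAR-H).

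Genes of the ERK pathway, which SHP2 feeds, did not pass the test singly. Of 25 measured genes of ERK pathway output, 0 rose, 0 fell and 25 did not pass. Adjusted over the list alone, the count was 0 in this and every other fixed list except the angiogenic factors. The differences of the ERK list were positive for 19 and negative for 6, with a list mean of 0.13. Of the 12053 genes left when classes of small non-coding genes are set aside, 7618 differences were positive and 4435 negative. Counts of positive differences, here and in the lists below, stand against that background. EGR1, an immediate early transcription factor induced by ERK, was 6.82 ± 0.10 in control and 7.23 ± 0.29 in knockdown tumours (difference 0.41, 95% interval 0.00 to 0.82). FOSL1, an AP-1 subunit, differed by 0.39 (SE 0.24), IER3 by 0.33 (SE 0.21) and the chromatin factor HMGA2 by -0.46 (SE 0.29), the last below the negative control percentile in all 6 arrays. The list as a whole missed the threshold in camera, which compares a list with all other genes (adjusted p = 0.075 with the preset correlation and 0.97 with an estimated correlation). Without knockdown 2 the list mean fell to 0.04 and the camera adjusted p was 0.89. The list passed in 4 of 19 alternatives. Without knockdown 1 the camera adjusted p was 0.011, and without both arrays numbered 1 it was 0.013, with list means of 0.24 and 0.16. The list also passed with arrays centred on their median (adjusted p = 0.037, list mean 0.09) and under the filter at the negative control percentile (0.018, list mean 0.19).

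Components of the SHP2 complex and of the RAS-ERK cascade also gave 0 of 21 genes past the threshold. NRAS differed by 0.32 (SE 0.19), the adaptor GRB2 by 0.29 (SE 0.19) and the exchange factor SOS1 by 0.20 (SE 0.17), while the docking protein GAB1, below the negative control percentile in all arrays, differed by -0.19 (SE 0.18). The list mean was 0.05 and changed sign, to -0.07, without control 1.

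Interferon response genes had higher values in knockdown tumours on balance, with the smallest camera p of the lists at the preset correlation. Of 24 measured members, 0 passed singly, and 21 differences were positive. The list mean was 0.25 and the camera adjusted p was 1.01e-04 with the preset correlation, but the adjusted p = 0.97 with an estimated correlation (unadjusted 0.19), and the same holds for fry, which tests whether a list's genes move one way on balance (adjusted p = 0.98). SAMD9L, an interferon-induced antiviral factor, was 5.31 ± 0.09 in control and 5.85 ± 0.13 in knockdown tumours, IFI35 was 5.02 ± 0.09 against 5.41 ± 0.13, and IFI27, below the negative control percentile in all arrays, was 4.42 ± 0.24 against 4.85 ± 0.10. The list mean was 0.16 without knockdown 3 and 0.37 without knockdown 1, and camera with the preset correlation passed in each of the 6 fits with 1 array left out. Antigen presentation genes, which share TAP1 and PSMB9 with this list, had positive differences for 12 of 12 members (list mean 0.25, camera adjusted p = 0.010, adjusted p = 0.97 with an estimated correlation), and 0 passed singly. The peptide transporter subunit TAP1 differed by 0.44 (SE 0.19), the immunoproteasome subunit PSMB8 by 0.45 (SE 0.25) and HLA-C by 0.33 (SE 0.24). The list's camera adjusted p was 0.39 without knockdown 3, 0.051 without control 3, 0.11 with no filter on low values, 0.095 with the filter at a log2 value of 6 and 0.062 with the covariate for the control contrast of the arrays. Its mean was 0.11 without knockdown 3 and reached 0.40 with another array left out.

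Chemokine and inflammatory genes gave 10 positive differences among 13 measured members, and 0 passed singly (list mean 0.28, camera adjusted p = 0.037, adjusted p = 0.97 with an estimated correlation). The leukocyte adhesion receptor ICAM1 was 5.99 ± 0.70 in control and 7.17 ± 0.95 in knockdown tumours, the caspase regulator BIRC3 4.82 ± 0.62 against 5.65 ± 0.49, and the monocyte chemoattractant CCL2 7.28 ± 0.49 against 7.92 ± 0.33. The camera adjusted p was 0.32, 0.052 and 0.20 without control 3, knockdown 1 and knockdown 3, 0.067 with no filter and 0.068 after quantile normalization. Cell cycle genes gave 30 positive differences among 34 members with 0 past the threshold (list mean 0.16, camera adjusted p = 0.017, adjusted p = 0.97 with an estimated correlation). The G1/S cyclin CCNE1 differed by 0.37 (SE 0.18), the mitotic motor KIF11 by 0.40 (SE 0.21), the mitotic kinase PLK1 by 0.46 (SE 0.25), and the replication helicase subunit MCM5 by 0.47 (SE 0.25). That list's adjusted p was 0.25, 0.10 and 0.70 without control 1, control 2 and knockdown 2, and its mean was 0.04 without control 1. The adjusted p was 0.19 with the filter at 6, 0.068 with the filter at the negative control percentile, 0.084 without both arrays numbered 1 and 0.58 with the covariate, where the mean was -0.0055.

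Hypoxia response genes had lower values in knockdown tumours on balance. Of 21 measured members, 18 differences were negative and 0 passed singly (list mean -0.18, camera adjusted p = 3.21e-04, adjusted p = 0.97 with an estimated correlation). The collagen lysyl hydroxylase PLOD2 was 8.33 ± 0.33 in control and 7.57 ± 0.71 in knockdown tumours, DDIT4, an inhibitor of mTORC1 signalling, was 6.33 ± 0.40 against 5.73 ± 0.56, the hypoxia-induced gene NDRG1 was 6.13 ± 0.23 against 5.78 ± 0.15, and the angiogenic factor VEGFA was 7.10 ± 0.29 against 6.67 ± 0.40. Without knockdown 2 the list mean was -0.04 and the camera adjusted p was 0.71. Glycolysis genes gave 12 negative differences among 18 (list mean -0.09, camera adjusted p = 0.046, adjusted p = 0.97 with an estimated correlation), with the glucose transporter gene SLC2A3 at -0.42 (SE 0.23, below the negative control percentile in all arrays), hexokinase HK2 at -0.33 (SE 0.26) and enolase ENO1 at -0.25 (SE 0.21). The camera adjusted p of that list was 0.14, 0.57, 0.16 and 0.95 without control 2, control 3, knockdown 1 and knockdown 2, and its mean was positive, 0.03 and 0.0033, without control 3 and knockdown 2. The adjusted p was 0.11 with no filter, 0.12 with the filter at 6, 0.060 with the feature of largest variance per gene and 0.10 with array weights.

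Ribosomal protein genes gave 23 negative differences among 29, and 0 passed singly (list mean -0.10, camera adjusted p = 7.24e-04, adjusted p = 0.97 with an estimated correlation). RPS6 was 5.82 ± 0.04 in control and 5.52 ± 0.06 in knockdown tumours and RPL37 was 6.24 ± 0.12 against 5.93 ± 0.14, while RPS4X, with a difference of -0.63, lay below the negative control percentile in all arrays. Ribosomal protein genes have many processed pseudogenes, which features can also read. The list mean was -0.03 and the adjusted p 0.051 without control 3. Extracellular matrix genes gave 15 negative and 14 positive differences among 29, with a list mean of -0.06 (camera adjusted p = 0.037, adjusted p = 0.97 with an estimated correlation). The proteoglycan versican, VCAN, was 8.75 ± 0.38 against 8.26 ± 0.16 and collagen COL12A1 was 9.60 ± 0.29 against 9.17 ± 0.22. That list's adjusted p was 0.14, 0.20 and 0.72 without control 2, control 3 and knockdown 1, and its mean was 0.05 without knockdown 1. The adjusted p was 0.067 with no filter, 0.073 with array weights and 0.42 without both arrays numbered 1.

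**Figure D3:**
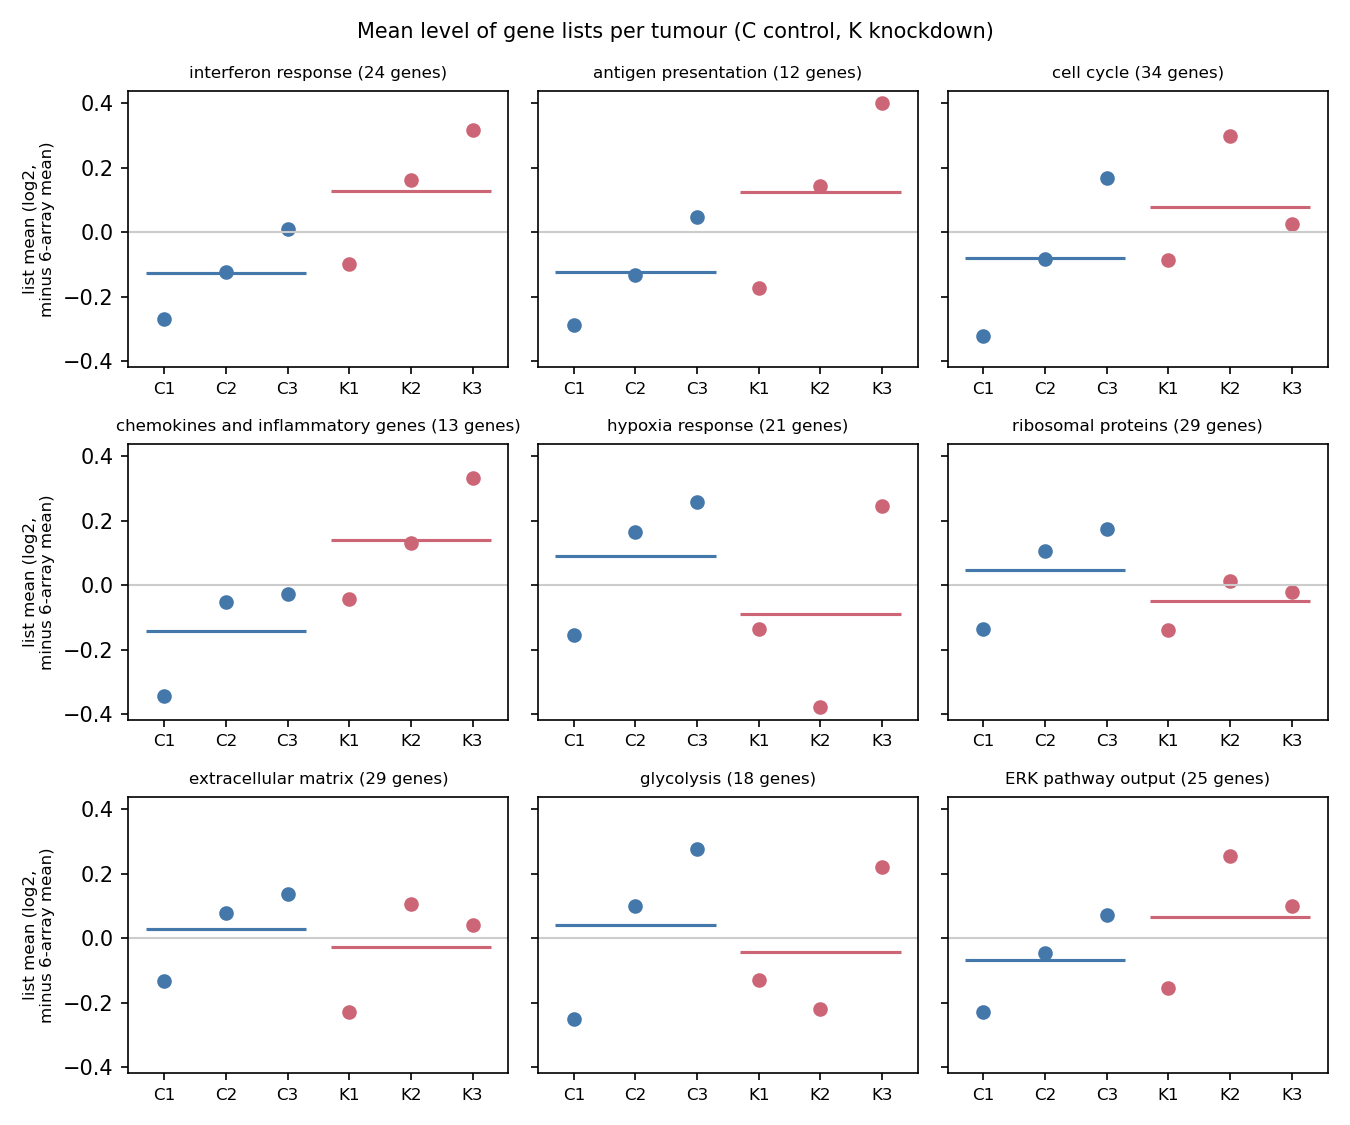
Mean log2 value of 9 gene lists in each tumour, minus the mean of that list over the 6 arrays (vertical axis), for control tumours (C1 to C3, blue) and knockdown tumours (K1 to K3, red), with a horizontal line at each group mean. Group means of the interferon list differ by 0.25 and those of the hypoxia list by -0.18, and in each of the 9 panels the points of the 2 groups overlap.

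Melanoma state and survival genes did not pass. Of 25 melanocyte differentiation genes 10 were measured, and 0 of these passed (camera adjusted p = 0.60), with ST3GAL6, a sialyltransferase gene, at -0.43 (SE 0.16) and the endothelin receptor EDNRB at -0.41 (SE 0.23), both below the negative control percentile in all arrays, and BCL2A1, an antiapoptotic target of MITF, at 0.55 (SE 0.31). Dedifferentiated melanoma genes gave 11 positive and 11 negative differences (camera adjusted p = 0.33), with the transcription factor POU3F2 at -0.31 (SE 0.16), NT5E, the ectonucleotidase CD73, at 0.39 (SE 0.22) and EGFR at 0.21 (SE 0.16). Among 20 apoptosis regulators 16 differences were positive (list mean 0.14, camera adjusted p = 0.15, and 0.034 under the filter at the negative control percentile), and besides BIRC3, above, the death receptors FAS and TNFRSF10B differed by 0.31 (SE 0.15) and 0.34 (SE 0.20). Among growth factors and receptor tyrosine kinases (camera adjusted p = 0.32), ERBB3, a neuregulin receptor, was 5.76 ± 0.61 in control and 4.77 ± 0.46 in knockdown tumours, and PDGFRA was 6.95 ± 0.04 against 7.48 ± 0.31. Among 15 angiogenic factors (camera adjusted p = 0.73), 1 gene passed when adjusted over the list alone and 0 over all genes tested. That list held NRP1, above, and the semaphorin SEMA3C, which was 8.05 ± 0.51 against 7.30 ± 0.25.

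The other tumour lists gave 0 genes past the threshold and no camera call. Their camera adjusted p was 0.32 for JAK-STAT feedback and cytokine receptors, 0.32 for FOXO and PI3K-AKT output, 0.77 for YAP and TAZ targets, 0.87 for p53 targets and for cholesterol and lipid synthesis, and 0.72 for the unfolded protein response. It was 0.94 for TGF-beta targets, WNT targets, oxidative phosphorylation and adhesion and motility, and 0.67 for matrix proteases. The matricellular gene CTGF, a YAP target, differed by -0.63 (SE 0.23), the cytokine receptors LIFR and IFNAR1 by 0.43 (SE 0.18) and 0.43 (SE 0.21), and TXNIP, a FOXO-responsive gene, by -0.57 (SE 0.22). Among p53 targets PHLDA3 differed by -0.37, AEN by 0.27, RRM2B by 0.39 and SESN2 by 0.40. The sterol isomerase EBP differed by 0.19 and the sterol desaturase SC5DL by -0.32, asparagine synthetase ASNS by 0.38 and the phosphatase subunit PPP1R15A by -0.26. The SMAD corepressor SKI differed by 0.30 and the integrin ITGA11 by 0.21, the WNT effector LEF1 by -0.32 and the WNT antagonist SFRP1 by 0.34. The respiratory chain subunit COX5B differed by -0.25 and the mitochondrial regulator PPARGC1A by -0.32, the integrin ITGA2 by 0.53, and the proteases MMP9 and CTSS by 0.43 and 0.72. Of the genes in this paragraph, TXNIP, PHLDA3, SESN2, EBP, ITGA11, COX5B, PPARGC1A and MMP9 exceeded the negative control percentile in 0 arrays. The FOXO list passed in camera without control 1 (adjusted p = 0.033, list mean -0.19) and without both arrays numbered 1 (0.016, list mean -0.18), and the cholesterol list with the covariate (0.014, list mean -0.15). These were 2 of 19 alternatives for the FOXO list. Its mean turned positive, 0.05, without control 3, and its camera adjusted p was 0.93 without knockdown 2. Because camera sets a list against all other genes, whose median difference was 0.05, the test ran downward with a positive list mean for YAP and TAZ targets, cholesterol and lipid synthesis, TGF-beta targets, oxidative phosphorylation, angiogenic factors and skeletal muscle markers. The dedifferentiated, melanocyte and FOXO lists had a positive median and a negative mean.

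Markers of other cell types, and the heat shock and immediate early genes listed for RNA quality, showed no gene past the threshold. RNA integrity itself was not measured here. The tumours grew in mice, so host cells are mouse cells, which a human array is not designed to measure. Reading of mouse RNA by these features was not tested, so host cell content was not tested either. Schwann and neural crest markers, some of which melanoma cells also express, gave negative differences for 6 of 6 measured members (list mean -0.29, camera adjusted p = 0.017, adjusted p = 0.97 with an estimated correlation), with S100B at -0.25 (SE 0.27), PMP22 at -0.13 (SE 0.21) and ERBB3, named above. That list's adjusted p was 0.35 without control 3 and 0.64 without knockdown 2. Its mean ran from -0.52 to -0.09 with 1 array left out. Endothelial, fibroblast and pericyte, and skeletal muscle markers had camera adjusted p of 0.96, 0.64 and 0.72, and heat shock and immediate early genes 0.32. Few markers of blood and skin cells passed the low-value filter on this human array: 3 of 18 for macrophages and monocytes, 3 of 12 for neutrophils, 4 of 15 for lymphocytes, 2 of 15 for keratinocytes, 1 of 10 for adipocytes and 2 of 10 for erythrocytes, too few for a list test. The mean list differences of these 6 sets were 0.07, 0.13, -0.05, -0.11, -0.12 and 0.06. CD68, the macrophage marker with the highest mean, was 7.30 ± 0.50 in control and 7.71 ± 0.63 in knockdown tumours. The endothelial marker ENG was 6.98 ± 0.43 against 7.29 ± 0.50 and EGFL7 was 5.18 ± 0.15 against 5.22 ± 0.16. The collagen gene COL1A1 was 7.90 ± 0.19 against 7.86 ± 0.15, the pericyte and melanoma proteoglycan CSPG4 7.40 ± 0.24 against 7.68 ± 0.45, and the chaperones HSPA8 and HSPB1 10.33 ± 0.14 against 10.36 ± 0.23 and 9.67 ± 0.22 against 9.91 ± 0.18. The markers C1QC, ELANE, LCN2, CD8A, CD79B, SFN, FLG, CKM, CFD and HBA1 exceeded the negative control percentile in 0 arrays, HBA2 in 1 and MYLPF in 2.

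The arrays differed within the groups in the contrast of positive and negative control features, which stands for array quality here. The source of this contrast was not tested. The median of positive control features minus that of negative control features was 3.64, 4.19 and 4.39 in control tumours 1 to 3 and 4.11, 4.44 and 4.47 in knockdown tumours 1 to 3, with group means of 4.07 and 4.34. The first principal component, which held 54.3% of the variance between the 6 arrays, followed this contrast (Pearson's r = 0.98, permutation p = 0.0083; Spearman's rho = 0.77, permutation p = 0.10; r = 0.89 without the 2 arrays farthest from the median). A correlation within each group was not computed, since each group holds 3 arrays. Of the 31 list means, 13 correlated with the contrast at an adjusted p under 0.05, all with a positive r. The mean of the 12053 genes outside the small non-coding classes did so too (r = 0.96, permutation p = 0.0069). A positive r is therefore not particular to a list, and list means were not set against all genes here. Lists not detailed below had r as high, such as heat shock and immediate early genes (0.98), matrix proteases (0.97) and the unfolded protein response (0.96). Among the lists described above, those of apoptosis regulators (r = 0.98), chemokine and inflammatory genes (r = 0.89), cell cycle genes (r = 0.88), ERK pathway output (r = 0.87), interferon response (r = 0.86) and antigen presentation (r = 0.84) had permutation p of 0.0014, 0.0028, 0.014, 0.019, 0.024 and 0.026 and adjusted values of 0.022, 0.027, 0.036, 0.046, 0.052 and 0.055 over 31 lists, so that the last 2 missed the threshold. Their Spearman's rho was 1.00, 0.94, 0.83, 0.94, 0.94 and 1.00, with permutation p of 0.0028, 0.017, 0.058, 0.017, 0.017 and 0.0028, and r without the 2 farthest arrays was 0.96, 0.76, 0.64, 0.78, 0.90 and 0.89. The hypoxia list did not follow it (r = 0.30, permutation p = 0.63; rho = 0.31, permutation p = 0.56; r = -0.23 without the 2 farthest arrays). With the contrast as a covariate, the PTPN11 difference was -2.16 (SE 0.22, adjusted p = 0.074 in limma), the interferon list mean was 0.12 and the hypoxia list mean was -0.31.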

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

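A signal outside the gene comparison was tested only after the main result was seen. Among 3320 features with no gene symbol or several that passed the low-value filter, limma called 1 (95 at an unadjusted p under 0.05). This feature, 16809913, is annotated in the deposited table as a small nucleolar RNA on chromosome 15, positions 58892331 to 58892434 of GRCh37. Its value was 4.81 ± 0.21 (SD, n = 3) in control and 2.73 ± 0.29 (SD, n = 3) in knockdown tumours, a difference of -2.08 (SE 0.21, adjusted p = 0.040 in limma), lower in 3 of 3 knockdown tumours. The feature lay below the 95th percentile of negative controls in all 6 arrays.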

How the results depend on the processing

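The covariate for the control contrast, the fit without both arrays numbered 1 and the filter at the negative control percentile were tests chosen only after the results were seen. The PTPN11 difference stayed negative in every alternative run, but its adjusted p missed the threshold with no filter on low values (-2.05, adjusted p = 0.079), after quantile normalization (-2.09, 0.077), with arrays centred on their median (-2.10, 0.084), without variance moderation (-2.05, 1.00) and with the control-contrast covariate (-2.16, 0.074); with 1 array left out it ran from -2.19 to -1.86, and the adjusted p from 0.021 to 0.27. Over all alternatives the adjusted p ran from 0.0013 to 1.00. In those 5 settings the count of genes, and of genes with a 2-fold change, was 0 in place of 1. Both counts ran from 0 to 1 with 1 array left out and were 2 without both arrays numbered 1. At a threshold of 0.1 and with every feature tested the count of genes stayed at 1. With the sample number as a replicate block it was 5, all lower in knockdown tumours: PTPN11, MIR644A, SNORD113-3, SNORD114-2 and SNX29P2 (adjusted p from 0.0013 to 0.026), the last 3 named after their values were seen. The numbers were not taken as pairs in the main fit. Deviations from the group means of same-numbered samples correlated at 0.42, -0.03 and 0.17, and 3 of 6 samples correlated best with their own number. With the block, however, the median residual variance was 0.031 against 0.051 in the main fit. The share of genes with an unadjusted limma p under 0.05 was 5.81% against 2.54%. The control contrast also rose from sample 1 to sample 3 in both groups, so a relation between same-numbered samples is not excluded. The 9 list calls became 5 with no filter, 4 with the filter at a log2 value of 6, and 0 both with an estimated correlation and with fry; they ran from 3 (without control 3) to 9 with 1 array left out, with 5 without knockdown 2. With the preset correlation the interferon list passed in 18 of 18 alternatives (the filter at 6 left too few members), the hypoxia and ribosomal lists in 18 of 19. The mean of the SHP2 and RAS-ERK component list (0.05) had a downward test with array weights (0.026), the covariate (-0.082) and without both arrays numbered 1 (-0.037), and ran from -0.068 to 0.15 with 1 array left out. The melanocyte list (-0.01) had an upward test under the negative control filter (0.073) and ran from -0.17 to 0.14. SESN2 (0.40) turned to -0.0097 without both arrays numbered 1, and PMP22 ran from -0.33 to 0.038. For the named genes other than PTPN11, all reported with an adjusted p of 1.00, keeping their side of the threshold shows little. Of 2244 values, 2241 kept their direction and that side, with 1 past it. Most named genes have 1 feature. Their difference could not change where only the filter, the feature chosen, the value table, the variance moderation or the block differed. Kept directions there show little too. For the described lists, direction is that of the list test, not the sign of the list mean. The melanocyte mean was positive, 0.015, with array weights and did not count as reversed. Of 257 list values, 200 kept that direction and their side, 44 lost the call, 5 gained it and 8 reversed. The cause of these changes was not tested, except that fewer arrays or added terms leave fewer degrees of freedom. Depth does not apply to arrays; 5 of the 20 genes named by p exceeded the negative control percentile in 0 arrays, so their size is limited by background.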

Other observations

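The tests of non-coding classes and GO terms, their relations with the control contrast, the fits with the contrast as a covariate, the list means relative to all genes and the tests of members that vary together were chosen only after the results were seen. Non-coding genes outside the fixed lists held several of the largest differences. Of 9 SNAR genes, small RNAs that bind NF90, 7 had positive differences and 6 an unadjusted limma p under 0.05, and the family mean was 7.54 ± 0.29 (SD, n = 3) in control and 8.08 ± 0.28 (SD, n = 3) in knockdown tumours (difference 0.54, exact two-sided permutation p = 0.2, 0.37 to 0.69 with 1 array left out, 0.72 with the covariate). Features of these near-identical copies can read the same transcripts, so the counts do not stand for independent genes. SNORD113 and SNORD114, snoRNA families of the imprinted region that also holds MEG3, had negative differences for 18 of 18 members, with a mean of -0.45 (6.53 ± 0.12 against 6.08 ± 0.53, exact permutation p = 0.3), -0.72 without knockdown 1, -0.19 without knockdown 3 and -0.25 with the covariate. MEG3 itself was 5.04 ± 0.52 against 4.26 ± 0.19, below the negative control percentile in all arrays. Other classes had mean differences of -0.12 (76 other SNORD genes), -0.28 (53 SNORA genes), -0.31 (16 SCARNA genes, exact permutation p = 0.1), -0.08 (204 microRNA genes), -0.13 (20 RNU genes) and -0.15 (92 RN5S genes), against 0.05 for the 12053 remaining genes. With the covariate the sign turned for microRNA genes (0.09), RN5S genes (0.08) and the remaining genes (-0.04), and the other means were -0.06 for other SNORD, -0.16 for SNORA, -0.26 for SCARNA and -0.05 for RNU. With 1 array left out the highest mean was 0.058 for microRNA, 0.047 for RNU and 0.0042 for RN5S genes, and the lowest for the remaining genes was -0.016. The adjusted p over the 9 classes was 0.7 for each, and 0.1 is the smallest unadjusted p that the design allows.

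Relations of the classes with the quality contrast depended on the measure: after adjustment over the 9 classes, RN5S and the remaining genes passed by Pearson's r but not by Spearman's rho (adjusted p = 0.175 for both), and SNORD113 and SNORD114 by rho (adjusted p = 0.025) but not by r. Over the 6 arrays the contrast correlated at r = -0.90 with the RN5S mean (permutation p = 0.0097; rho = -0.83, permutation p = 0.058; r = -0.81 without the 2 farthest arrays) and at r = -0.89 with the microRNA mean (permutation p = 0.017; rho = -0.71, permutation p = 0.14; r = -0.58). For the remaining genes r was 0.96 (permutation p = 0.0069; rho = 0.83, permutation p = 0.058; r = 0.80). The adjusted p of r over the 9 classes was 0.044, 0.050 and 0.044 for these 3, so that the microRNA mean lay at the threshold and did not pass. It was 0.87 for SNAR (r = -0.08), 0.185 for SNORD113 and SNORD114 (r = -0.70) and for SNORA (r = -0.71), 0.28 for other SNORD (r = -0.59) and SCARNA (r = -0.58), and 0.33 for RNU (r = -0.48). The permutation p of these was 0.87, 0.10, 0.097, 0.22, 0.21 and 0.29 in that order. Their rho was -0.26, -1, -0.77, -0.77, -0.66 and -0.66, with permutation p of 0.66, 0.0028, 0.10, 0.10, 0.175 and 0.175, and r without the 2 farthest arrays was 0.29, -0.75, -0.89, -0.84, -0.89 and -0.58. MIR1185-2 was 9.13, 7.86 and 5.64 in control tumours 1 to 3 and 9.08, 5.35 and 5.59 in knockdown tumours 1 to 3, the largest spread within groups among genes above the negative control percentile in all arrays. Among 1061 GO process terms of the deposited table, 10 passed in camera with the preset correlation and 0 with an estimated one. Viral transcription, a term of mostly ribosomal protein genes, had a median of -0.07 over 62 genes (adjusted p = 0.011, and 3.32e-05 with the contrast as a covariate), and antigen presentation of exogenous peptide via MHC class I a median of 0.16 over 64 genes (adjusted p = 0.011, and 0.73 with the covariate).

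Only PTPN11 passed the threshold. The simulated data gave calls for most changes of 1 log2 unit, but held many changed genes, which makes the adjustment less strict. They therefore cannot tell whether lone changes of that size would pass here. SNAR-H, with a difference of 1.06 and an unadjusted limma p of 0.00097, did not pass. A candidate explanation for the low count is the difference in array quality within groups. With the control contrast as a covariate the median residual variance fell by 50.7%, the share of genes with an unadjusted p under 0.05 went from 2.54% to 5.22%, and 0 genes passed. A count of 3 or fewer was to speak against array quality, but PTPN11 itself missed the threshold in that fit (adjusted p = 0.074, 3 residual degrees of freedom), so the count decides nothing and array quality stays open. Of the 10 splits of the 6 arrays, 2 with the real one included gave at least as many genes (1 in the real split), and likewise 2 for genes with a 2-fold change (1), the highest other being 50 and 35, for the split that puts the 3 arrays of lowest contrast (control 1, control 2 and knockdown 1) against the rest, which points to a structure of the samples. The 10 splits are too few for a share under 0.05, and an effect of the knockdown on other transcripts stays open, as untested.

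The interferon list was higher in knockdown tumours by 0.25. With the covariate the list mean was 0.125 (SE 0.10), just under 50% of the unadjusted value, which meets the bound set beforehand for array quality as the cause. With that SE the mean can lie on either side of the bound. Relative to the mean of all genes, which the covariate also moved, it was 0.16 (SE 0.10) against 0.21 (SE 0.09), 77.6%, a measure chosen after the results were seen. The camera adjusted p with the preset correlation was 5.35e-04 in the covariate fit. Array quality therefore cannot be told apart from a group difference. Members that vary together between tumours also fit, since the camera p was 3.25e-06 with the preset correlation and 0.19 with an estimated correlation of 0.42 between members. Whether 1 array decides it cannot be told apart from a difference of the groups, since the smallest mean with 1 array left out was 0.159, between the bounds set beforehand. For the count of list calls, 2 of the 10 splits, the real one included, gave 9 lists or more (9 in the real split, 9 in the highest other), and the splits are too few for a share under 0.05; an effect of the knockdown or of the hairpin itself stays open, as untested.

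The hypoxia list was lower in knockdown tumours by 0.18 on the log2 scale. Here 1 array may decide the difference: without knockdown 2 the mean was -0.036. Members of this list varied together between tumours too, with an estimated correlation of 0.60 and a camera p of 0.26, against 2.07e-05 with the preset correlation. As for the interferon list, that test cannot decide, since no list gave a p under 0.178 in camera with an estimated correlation. Array quality is not excluded, since the mean was -0.315 (SE 0.23) with the covariate, and relative to the mean of all genes -0.28 (SE 0.25) against -0.22 (SE 0.20), with a camera adjusted p of 4.06e-04 at the preset correlation, larger than without it but with an SE that reaches below 50% of the unadjusted value. A difference between tumours in size or blood supply was not tested.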
